A study of Mus musculus with 6 samples.

How the data were processed

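The series holds cap analysis of gene expression (CAGE) libraries of Ba/F3 cells, a mouse pro-B cell line widely used to study oncogenic kinases because it survives without its usual cytokine once such a kinase is introduced. CAGE sequences the capped 5′ ends of RNA, so that each tag marks a transcription start and a peak of tags marks a promoter. Per the labels' protocols, total RNA was taken with a column kit and the libraries were made by the no-amplification non-tagging variant of CAGE. The 6 libraries fall into 2 groups of 3 by their titles. In 1 group the cells carry FLT3-ITD, an internal tandem duplication in the FLT3 receptor tyrosine kinase. In the other they carry FLT3-ITD together with D835Y, a substitution in the kinase's activation loop, and that group is called the double mutant here. A second label gives the position of the substitution as a number that goes up by 1 from sample to sample, so the titles were used. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

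Each deposited table lists the same 158966 peaks, named only by chromosome, position and strand, with 1 value per peak. The deposited values are CPM made by the authors, tags scaled to a common total over the peaks of that library, and each table sums to 1000000. Per the submitters' processing notes the tools used included TopHat2 2.0.14 and edgeR 3.24.3, and the genome builds named are hg19 and mm9, with no role given to any of them. How tags were filtered and how the peak list was made is not given in the sources used here. In every library, 100% of the deposited CPM values were whole multiples of the smallest value above 0, within a tolerance of 0.01 of a multiple. The tag numbers recovered in this way were between 5884258 and 13977941 per library, which puts the value of 1 tag between 0.0715 and 0.170 CPM. A count of 0 in 1 library allows a level of up to 0.215 to 0.510 CPM, the value of 3 tags. Such floors and intervals cover counting error only.

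Coordinates are given as deposited, and whether starts count from 0 or 1 is not stated. The mouse build named in the notes is mm9. The gene table used for names follows another build, GRCm38: 53 peaks on chromosome 1 and 1294 on chromosome 7 lie past its last gene. Coordinates were not converted between builds. The files do not pair peaks with genes, so promoters are named by position and no gene is named. For this reason the planned tests per gene, of promoter usage within genes, of 23 gene lists and of the Flt3 promoter were not made, and 0 of the 23 lists were tested. The words promoter and peak are used for the same thing below. Peaks on M (247) and Y (32) held 0 tags in every library and played no part.

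The test planned before the data were examined was edgeR's quasi-likelihood test on counts, with limma on log2 values in its place should the files hold a normalized unit. Since the deposited unit is CPM, promoters were tested with limma 3.58.1 (trend and robust options) in R 4.3.3 on log2(CPM + 1), with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All p-values are two-sided. Promoters entered when they reached 1 CPM in at least 3 libraries, which left 19162 promoters, holding over 99% of the tags in each library. Differences are given as double mutant minus FLT3-ITD on the log2(CPM + 1) scale, which understates the change of low promoters. Count tests on the recovered tags (edgeR 4.0.16, DESeq2 1.42.0, limma-voom) served as alternatives only.

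Those called named promoters below follow a rule set before the data were examined. The rule takes promoters past the threshold, with a mean of at least 5 CPM after TMM scaling and with groups that do not overlap. Of these it names the 5 with the largest rise and the 5 with the largest fall. Other promoters given by position lie outside that rule and were picked after their values were seen. Chromosomes were compared with camera, each chromosome's promoters against all others, with a preset correlation of 0.01 and with an estimated one. Added after seeing the data were windows of 50 consecutive tested promoters, tested with limma on the mean of each window after each library was centred on its mean over all tested promoters, promoters with tags in 1 group only, pairs of promoters at most 1000 bp apart, the regions of chromosomes 13, 15 and X, and runs of strongly changed promoters. Ratios of pooled tags carry exact 95% intervals.

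The promoter test was tried on simulated values with the means and depths of this comparison and 1 dispersion for all promoters. The changed promoters were drawn from those with a mean above 2 CPM. Of 100 changed by a fold of 2, 80% were recovered, and of 100 changed by a fold of 4, 100%. There were 10 false calls among the 19162 promoters. Recovery of lower promoters, and loci that vary more within groups, were not tried. A simulated shift of 0.3 (log2) on chromosome 19 was called, 0 other chromosomes were called, and 15 of 15 windows on 19 and 1 of the 359 other windows passed. All simulated promoters varied independently, so false calls where promoters of a chromosome vary together were not measured. On real values, splits of the libraries other than the real one called up to 6 chromosomes. Alternatives covered the scaling, the filter, the pseudocount, the tool, a fold threshold, a term for the replicate number, the correlation used by camera, the window size and summary, and leaving out each library in turn, keeping the tested promoters. Figures were drawn with matplotlib 3.10.9.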

Results

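CAGE promoter levels were measured in Ba/F3 cells with FLT3-ITD (n = 3) and in Ba/F3 cells with FLT3-ITD plus D835Y (n = 3). The FLT3-ITD libraries held 10256280, 5884258 and 11397865 tags, and the double-mutant libraries 11918244, 13977941 and 10114212. A tag was seen at between 34672 and 41984 of the 158966 peaks per library. Libraries of the same group correlated more closely across promoters (Pearson's r of log2 values 0.980 to 0.988) than libraries of different groups (0.945 to 0.962), where promoters are not independent replicates. Within groups, tags differed between libraries by 3.77 to 20.2 times the sampling variance, so no library repeated another. Between groups the values were 17.2 to 47.4, so the ranges overlapped. This measure grows with depth. The lowest values between groups, 17.2 and 17.6, both involved FLT3-ITD replicate 2, which had the fewest tags. The highest values within groups, 19.6 and 20.2, both involved double-mutant replicate 2, which had the most tags. Double-mutant replicates 1 and 3 gave 5.80.

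The series was made to find promoters that differ between the FLT3-ITD cells and the double mutant. Of 19162 promoters tested, 4680 (24.4%) changed, 2695 higher and 1985 lower in the double mutant (limma, adjusted p under 0.05). The typical change was moderate, with a median size of 0.71 on the log2 scale among promoters that changed, and 612 rose and 456 fell by at least 1. The groups did not overlap at 41.8% of the tested promoters, where chance gives 10%. Change was seen at every level of activity: 18.9% of the least active tertile, 25.7% of the middle and 28.6% of the most active tertile passed. The count was 3076 without FLT3-ITD replicate 2 and 550 against a fold of 1.5. Among the 10250 promoters with a mean of at least 5 CPM, 2916 changed. The number that fell was 1215 without FLT3-ITD replicate 3. Higher promoters made up 57.6% of the changed ones but 49.8% after TMM scaling and 48.1% with DESeq2, so the data did not settle whether more promoters rose than fell.

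The promoters with the largest rise were close to silent in FLT3-ITD cells. On chromosome 11, the plus-strand promoter at 4216159 to 4216171 (chr11:4216159..4216171,+) went from 0.058 ± 0.10 to 45.6 ± 4.1 CPM (SD, n = 3 each), a log2 change of 5.46 (SE 0.16, limma adjusted p = 8.5e-10). It had 2 tags in the pooled FLT3-ITD libraries and 1632 in the pooled double-mutant libraries, a ratio of 624 with an exact 95% interval of 172 to 5157. The minus-strand promoter of chromosome 1 at 172989479 to 172989510 rose from 0.24 ± 0.090 to 30.3 ± 2.5 CPM. Both named promoters on chromosome 7 rose, the plus-strand promoter at 29581028 to 29581089 from 0.24 ± 0.33 to 25.8 ± 5.2 CPM and the minus-strand promoter at 135039092 to 135039161 from 0 tags in every FLT3-ITD library to 16.2 ± 1.2 CPM. The mean of the last was over 148 times the level of 3 tags in the pooled FLT3-ITD libraries (0.109 CPM). The exact 95% interval of its ratio of pooled tags, 579 against 0, starts at 119.6. The minus-strand promoter of chromosome 3 at 68848619 to 68848685 rose from 0.12 ± 0.20 to 18.3 ± 5.0 CPM. Across these 5, limma's adjusted p ranged from 8.5e-10 to 5.6e-08.

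Promoters with the largest fall were well expressed in FLT3-ITD cells and low in the double mutant. The plus-strand promoter of chromosome 4 at 145022324 to 145022347 fell from 100.0 ± 8.2 to 2.1 ± 1.8 CPM (SD, n = 3 each), a log2 change of -5.22 (SE 0.55, limma adjusted p = 0.0037). The plus-strand promoter of chromosome 13 at 98252702 to 98252714 fell from 130.2 ± 14.9 to 4.3 ± 3.7 CPM, and the minus-strand promoter of chromosome 3 at 135271185 to 135271254 from 84.5 ± 3.3 to 2.6 ± 2.1 CPM. On chromosome 4, the minus-strand promoter at 140330111 to 140330127 fell from 54.9 ± 0.99 to 2.8 ± 2.3 CPM, and the plus-strand promoter at 148960541 to 148960620 from 17.5 ± 0.96 to 0.13 ± 0.15 CPM, with 486 against 4 pooled tags. At the first 4 of these, double-mutant replicate 2 stood below the other replicates: at 145022324 its level was 0.21 CPM, against 3.69 in replicate 1 and 2.47 in replicate 3. Against a fold of 1.5, the call ended for the promoter at 98252702 (limma adjusted p = 0.064) and for that at 140330111 (adjusted p = 0.056), whose adjusted p was at or under those values in all alternatives.

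**Figure D1:**
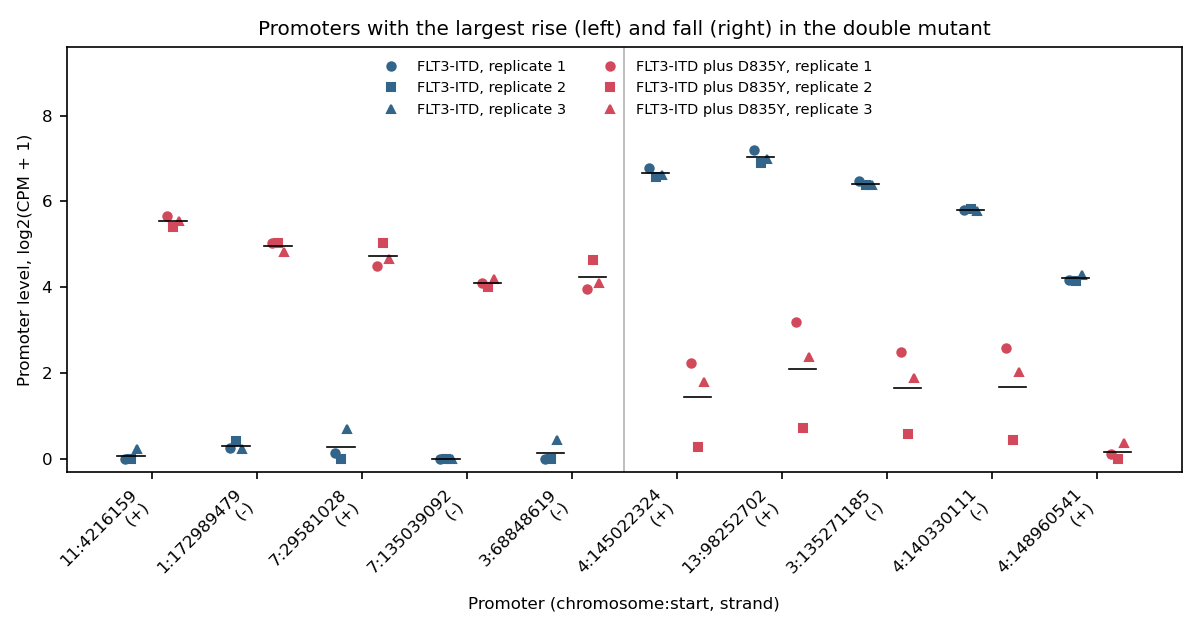
Level of the 10 named promoters in each library, on a log2(CPM + 1) axis, with blue for FLT3-ITD, red for the double mutant, a symbol per replicate and a black line at each group's mean of log2 values. The groups are separate at all 10, and at the first 4 promoters that fell the square of double-mutant replicate 2 lies lowest.

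Some promoters had tags in 1 group alone. With at least 1 CPM in all 3 libraries of a group and 0 tags in all 3 of the other, 37 promoters were present in the double mutant only, at 1.30 to 16.2 CPM, and 6 in FLT3-ITD only, at 1.20 to 2.91 CPM. Of the 37, 10 lay on chromosome 7 and 8 on chromosome 11, which held 1476 and 1669 of the 19162 tested promoters, and whether this exceeds chance was not tested. Leaving out a library relaxes the definition, so these counts can then only stay or rise. They were 65 and 19 without FLT3-ITD replicate 3, the second count was 20 without double-mutant replicate 1, and 11 without double-mutant replicate 3.

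Promoters close to one another mostly changed in the same direction. Among pairs on the same strand at most 1000 bp apart in which both promoters changed, 554 of 569 moved together, as did 93 of 99 pairs on opposite strands. The remaining 15 same-strand pairs moved apart. On the minus strand of chromosome 11, the promoter at 3309119 to 3309162 rose from 8.52 ± 0.86 to 15.9 ± 3.0 CPM (SD, n = 3 each; limma adjusted p = 0.0030), while its neighbour at 3309165 to 3309198 fell from 2.77 ± 1.44 to 0.56 ± 0.10 CPM (adjusted p = 0.0030). On the plus strand of chromosome 9, the promoter at 19426523 to 19426584 fell from 29.4 ± 3.6 to 12.9 ± 0.59 CPM and that at 19426741 to 19426775 rose from 1.19 ± 0.15 to 2.65 ± 0.14 CPM. On the minus strand of chromosome 1, the promoter at 88254786 to 88254807 fell from 78.3 ± 15.2 to 33.2 ± 7.3 CPM and that at 88255545 to 88255572 rose from 23.9 ± 2.0 to 36.0 ± 1.0 CPM. These 3 pairs were picked after their values were seen, among those whose members moved furthest apart.

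Whole chromosomes differed between the groups. Mean differences of chromosomes were taken after each library was centred on its mean over all tested promoters, while counts of changed promoters were taken without centring. Promoters of chromosome 19 were higher in the double mutant by a mean of 0.37 (log2, SE 0.010), and 363 of its 795 promoters rose while 21 fell. Promoters of chromosome 9 were lower by a mean of -0.29 (SE 0.034), with 304 of 1136 lower and 37 higher. Chromosomes 12 (0.19), 8 (0.13) and 2 (0.10) were also higher, and chromosomes 10 (-0.21), 13 (-0.21), 5 (-0.20) and 14 (-0.12) lower. In all, 9 of 20 chromosomes passed camera with the preset correlation, with adjusted p from 3.6e-14 for chromosome 19 and 1.1e-11 for chromosome 9 to 0.028 for chromosome 2. With an estimated correlation 0 passed and 4 had an unadjusted p under 0.05: the adjusted p was 0.095 for chromosomes 19 and 9, 0.14 for chromosome 13, 0.23 for chromosomes 10 and 5, 0.38 for chromosomes 12 and 14, 0.46 for chromosome 8 and 0.53 for chromosome 2. With no filter on low values 6 chromosomes passed, and the mean difference was 0.16 for chromosome 19 and -0.13 for chromosome 9. The mean level of the chromosome separated the 3 libraries of 1 group from the 3 of the other for 19 of the 20 chromosomes.

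**Figure D2:**
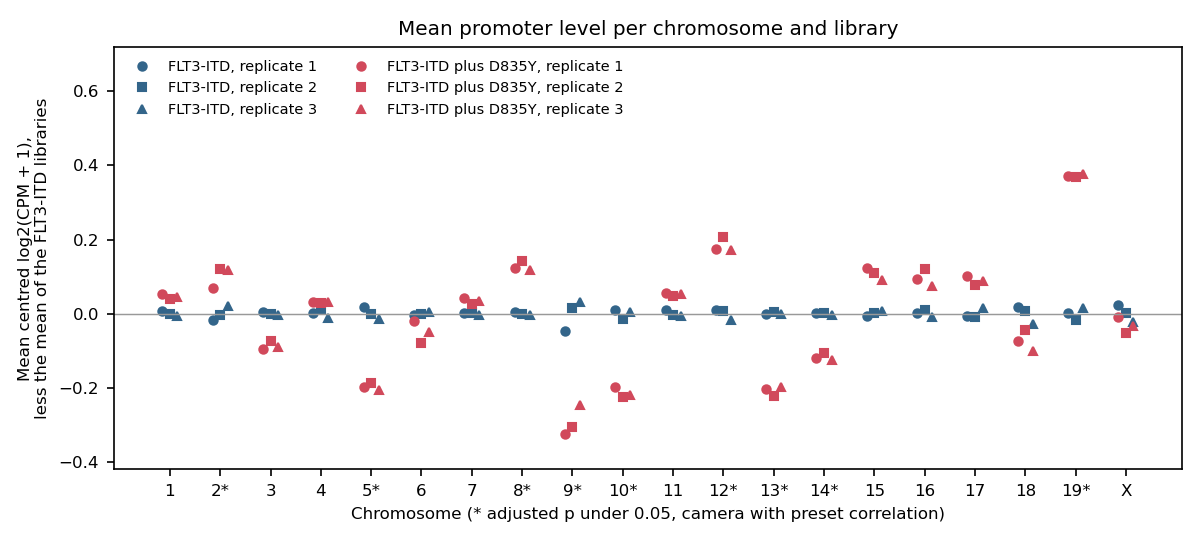
Mean centred log2(CPM + 1) of each chromosome's promoters in each library, less the mean of the FLT3-ITD libraries, with blue for FLT3-ITD, red for the double mutant and a symbol per replicate. Chromosome 19 lies highest in all 3 double-mutant libraries (mean difference 0.37) and chromosome 9 lowest (-0.29), and asterisks mark the 9 chromosomes past the threshold with the preset correlation.

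Within chromosomes, the means of neighbouring windows often differed in the same direction, and in places the direction changed. The mean of a window can rest on some of its promoters only. Of 374 windows of 50 promoters, 276 differed, 141 higher and 135 lower in the double mutant (limma adjusted p under 0.05). All 15 windows of chromosome 19 were higher and all 18 of chromosome 10 lower, as were 22 of 23 on chromosome 5, 20 of 22 on chromosome 9 and 13 of 14 on chromosome 13. Chromosome 3 was higher in its first window, from 5.58 Mb (0.18), and lower in the next, from 27.1 to 37.6 Mb (-0.29). It was higher again in the 6 windows from 39.3 to 90.3 Mb (mean 0.20) and lower in the 10 windows from there to 159.5 Mb (mean -0.26). Chromosome 14 was higher from 8.65 to 27.5 Mb (mean 0.18) and lower in the 10 windows beyond (mean -0.18). Chromosome 4 was lower in the 3 windows from 137.8 to 150.3 Mb (mean -0.39) and higher in the last, from 150.4 to 155.6 Mb (0.40). Chromosome 17 was lower in its first 4 windows, up to 25.3 Mb (mean -0.19), and had 10 higher windows beyond. On chromosome 6 a window from 72.9 to 83.5 Mb was higher by 0.44, and the 3 windows from 83.7 to 100.6 Mb were lower (mean -0.32). The count of windows was 159 with medians in place of means. It was 149 among the 10250 promoters with a mean of at least 5 CPM, which form fewer windows than the 374.

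**Figure D3:**
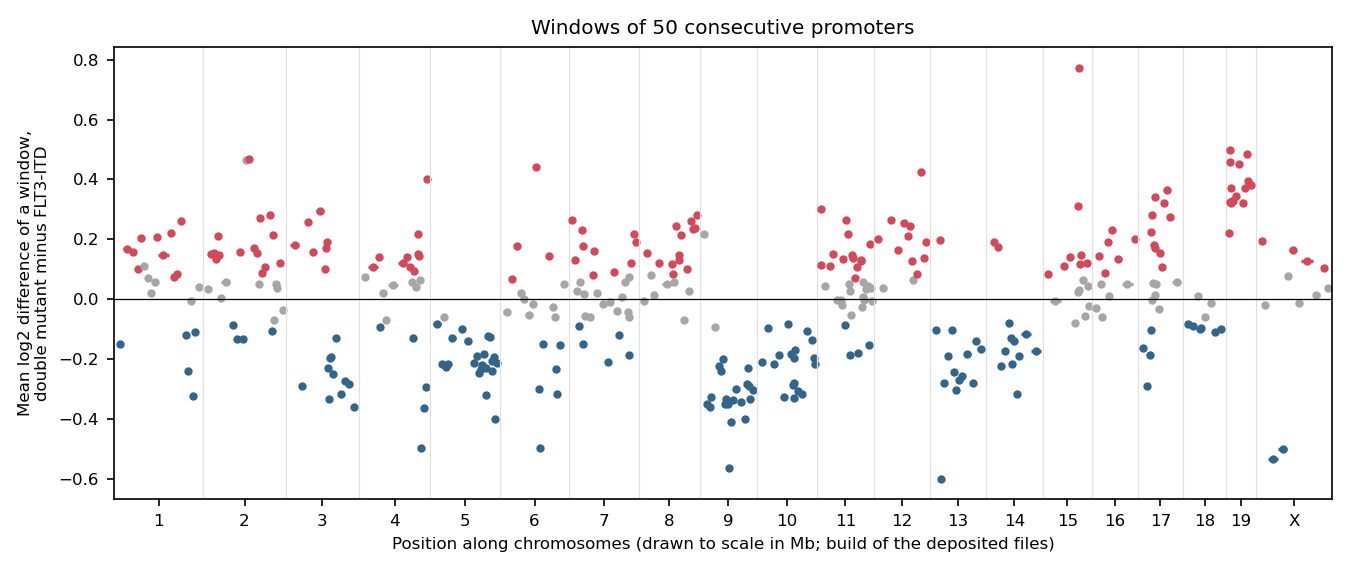
Mean log2 difference, double mutant minus FLT3-ITD, of 374 windows of consecutive promoters along the chromosomes, with red for windows that were higher, blue for windows that were lower and grey for those that did not pass. Chromosome 19 is higher throughout, chromosome 10 lower throughout, and chromosomes 3, 4 and 14 change sign part of the way along.

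A block of chromosome 13 that held the single most active promoter of the data was lower in the double mutant. Between 23622786 and 23714432, 24 of 31 promoters fell and 0 rose, with a median change of -0.71 (quartiles -1.03 and -0.51). Together they held 70268 ± 3101 CPM in FLT3-ITD cells and 43899 ± 1789 CPM in the double mutant (SD, n = 3 each). The plus-strand promoter at 23673432 to 23673438 (chr13:23673432..23673438,+) fell from 15946 ± 1143 to 8648 ± 594 CPM (SE of the log2 change 0.11, limma adjusted p = 8.5e-05). Of the 13 promoters in the block with a mean of at least 1000 CPM, 12 fell, and the remaining one, at 23627280 to 23627296, had 2305 ± 240 and 2032 ± 132 CPM (adjusted p = 0.27). Just beyond the block, from 23775810 to 23855543, 4 of 18 promoters fell and 1 rose (limma, adjusted p under 0.05; median -0.13), and of the 9 that were that active 1 fell and 1 rose (median -0.02). Between 21808044 and 22135077, 2 of 25 promoters fell and 2 rose. Of the 16 that were that active 0 fell and 2 rose (median 0.00), with 4 of them in near-identical pairs. From there to the block, the minus-strand promoter at 23515705 to 23515753 also fell, by -0.74 (limma adjusted p = 0.0037). The other tested promoters of that stretch did not pass.

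**Figure D4:**
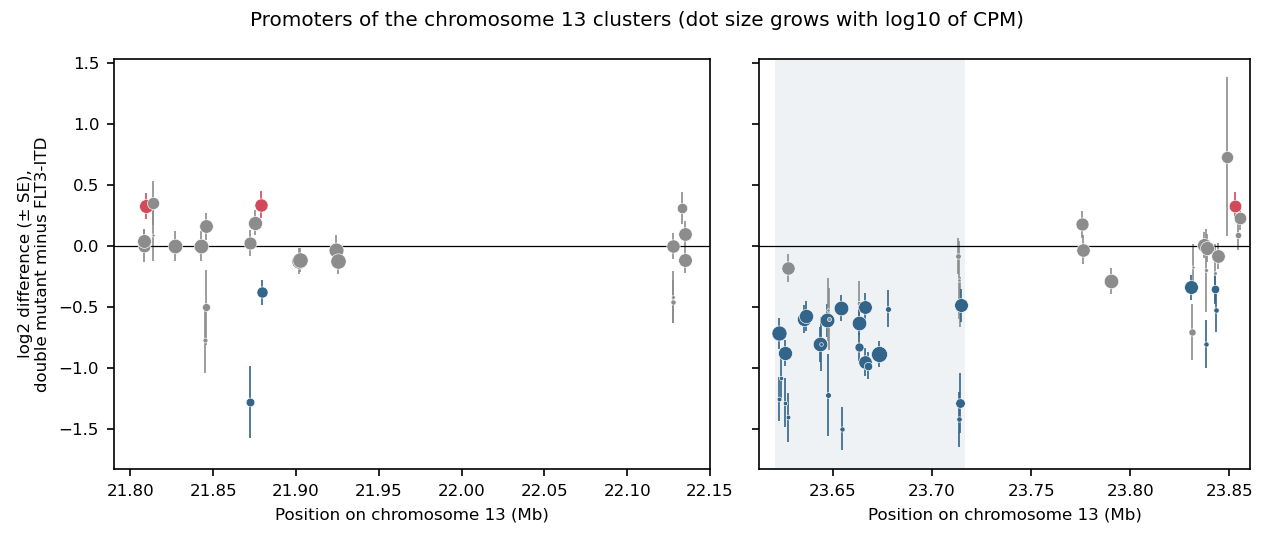
Log2 difference with its SE, double mutant minus FLT3-ITD, of promoters in both clusters of chromosome 13, against position in Mb, with blue for promoters that fell, red for those that rose and grey for those that did not pass; dot size grows with activity and the block is shaded. All but 7 of the 31 promoters in the shaded block fell.

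On chromosome X, a segment was lower in the double mutant. From 23270169 to 50623035, 47 of 78 promoters fell and 4 rose, with a median change of -0.64, and their summed level was 4525 ± 167 CPM in FLT3-ITD cells and 3235 ± 381 CPM in the double mutant (SD, n = 3 each). Of the 100 promoters before it, from 6896312, 15 rose and 4 fell (median 0.21). Of the 22 promoters beyond the segment, from 53708096 to 66859468, 4 rose and 3 fell (median 0.02, mean -0.12), and of 150 promoters from 67618103 to 98848897, 14 rose and 5 fell (median 0.16). Over all of chromosome X the mean difference was -0.03 after each library was centred on its mean over all tested promoters. The median change was 0.12 without centring, as are the region values above, so these are not on 1 scale. Camera placed the chromosome higher, with an adjusted p of 0.78. The bounds of these regions of chromosomes 13 and X were set after the values were seen.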

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

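Alternatives with TMM scaling, edgeR, another pseudocount, chromosome or window means removed, another window size or summary, or another minimum level were chosen after seeing the data, the others before. Of 190 refits of the 10 named promoters, 188 kept the direction and the side of the threshold and 2, both against a fold of 1.5, lost only the call. The number of changed promoters was 4680, and 4904 with RLE and 4900 with TMM scaling, 4710 with edgeR, 4588 with limma-voom and 3538 with DESeq2, where 1702 were higher and the cause was not tested. It was 2916 among promoters with a mean of at least 5 CPM (1657 higher, 1259 lower), where 10250 were tested, and 550 against a fold of 1.5 (347 higher, 203 lower). With chromosome means removed it was 3658 and with window means removed 3383, and 3233 and 2765 of these were among the 4680. Under these 2 settings 5 and 46 of the 4680 had a change of opposite sign. Leaving out single libraries gave 3076 (without FLT3-ITD replicate 2) to 5209 (without double-mutant replicate 2) changed promoters, 1807 to 2745 higher and 1215 to 2464 lower, and 2985 to 4124 of them were among the 4680, and the cause was not tested. With an estimated correlation 0 chromosomes passed in place of 9. Camera then estimates from the data how far promoters of 1 chromosome vary together, in place of the preset 0.01. Left-out libraries, with the preset correlation, gave 9 to 11. With no filter on low values 6 passed, with mean differences of 0.16 for chromosome 19 and -0.13 for chromosome 9, and with a mean of at least 5 CPM 13 passed. Windows passed in 149 cases with a mean of at least 5 CPM, 499 with windows of 25 promoters, 137 with windows of 100 and 159 with medians; the first 3 settings change how many windows there are, and the cause of the last was not tested. Left-out libraries gave 251 to 275. Promoters in the double mutant only numbered 76 at a minimum of 0.5 CPM, 16 at 2 CPM and 40 to 65 with a library left out; those in FLT3-ITD only numbered 15, 2 and 7 to 20, since the definition asks for 0 tags in fewer libraries or another level. With a term for the replicate number (replicate block), 4109 promoters changed. The numbers were not taken to pair the libraries: deviations of same-numbered libraries correlated at -0.01, 0.02 and 0.19, and not every library correlated best with its own number. At the loci of chromosomes 2 and 9 that varied widely within groups, the double mutant was higher in all 3 same-numbered pairs, and 17 of 28 and 10 of 39 promoters changed with that term, against 1 and 1 without it, a hint from the data and not the design. Depth limits low promoters, since 1 tag is worth up to 0.170 CPM.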

Other observations

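Runs of consecutive promoters that moved together by at least 1 (log2) marked 4 loci, a search made after seeing the data. Each run had at least 5 promoters, all past the threshold (limma, adjusted p under 0.05) and at most 50000 bp apart. Of these runs, 3 were higher and 1 lower in the double mutant. In 1000 shuffles of promoter order within chromosomes there was at most 1. The shuffles also part close neighbours, which mostly moved together, so they do not bound what such neighbours alone would give. The run with the most promoters, 10, lay on chromosome 15. Over the wider locus from 78114550 to 78179623, 17 of 17 tested promoters on both strands were higher, 15 of them past the threshold, with log2 changes of 1.07 to 2.99. Their summed levels were 134, 145 and 168 CPM in the FLT3-ITD libraries and 1634, 1326 and 487 CPM in the double-mutant libraries. The minus-strand promoter at 78136068 to 78136100 rose from 6.72 ± 1.02 to 60.3 ± 6.1 CPM (SD, n = 3 each; limma adjusted p = 2.7e-08). The most active one, on the plus strand at 78156474 to 78156489, had 123 ± 11 and 958 ± 576 CPM and did not pass (adjusted p = 0.056).

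The other runs had 5 promoters each. On the minus strand of chromosome 1, 5 promoters from 108608936 to 108610907 rose from a summed 42.7 ± 5.7 to 175 ± 16 CPM. On the plus strand of chromosome 11, 5 promoters from 4120705 to 4216171, the most strongly risen named promoter among them, went from 3.94 ± 0.25 to 86.1 ± 5.9 CPM. On the minus strand of chromosome 8, 5 promoters from 125951545 to 125956462 fell from 14.1 ± 2.6 to 0.49 ± 0.41 CPM. At 2 further loci the libraries differed widely within both groups. The 28 promoters of chromosome 2 from 98502406 to 98507439 summed to 85.6, 682 and 1314 CPM in the FLT3-ITD libraries and 368, 897 and 2856 CPM in the double-mutant libraries, and the 39 promoters of chromosome 9 from 3000035 to 3038198 to 25.5, 178 and 325 CPM and 70.6, 203 and 600 CPM.

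For the weighing that follows, the splits of the libraries, the shares of promoters above the median change, the test of promoter level on chromosome 9 and the tests on the chromosome 13 block and on residual levels were chosen after the result was seen. The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 4680 promoters and the highest other 1, 9 chromosomes and the highest other 6, and 276 windows and the highest other 0 (limma adjusted p under 0.05). In each of these 3 results 1 split, the real one, reached its value.

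A few strongly changed promoters as the whole of the shifts are argued against, since 82.3% of all promoters of chromosome 19 and 21.1% of those of chromosome 9 lay above the median change of all promoters; among the 1206 that did not pass the test, a set that the change itself decides, the chromosomes differed by 0.27 (SE 0.052), against 0.67 over all. Compared with 10000 random sets of promoters of like level from other chromosomes, chromosome 19 stood higher by 0.39 and above all of them, and chromosome 9 lower by -0.31 and below all of its own 10000, so a bias that follows promoter level is argued against for both, although on chromosome 9 the difference grew with level (-0.20, -0.32 and -0.39 by tertile). The SD among windows within chromosomes was 0.15, where 1000 shuffles of promoter order reached at most 0.082. Promoters changing independently of their neighbours would not give it. The shuffles also part neighbours at most 1000 bp apart, which mostly moved together, so this alone does not show that longer segments move. What stays open is a difference in chromosome copy number between the cell lines: relative to all promoters, chromosome 19 was higher in each tertile of promoter level, by 0.30 to 0.45, as a change in dose may give. No DNA was measured, GC content could not be tested, and D835Y itself stays untested since no second pair of lines was given.

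For the block of chromosome 13, a lower yield of very active promoters in general is argued against: 142 promoters with a mean of at least 1000 CPM elsewhere had a median change of 0.062, where the 13 in the block had -0.61. Tags shared between near-identical copies could be tested only in part. Of those 13, 0 belonged to the 7 pairs of promoters whose levels stayed within 2% of each other in all libraries. Copies that share tags unequally would not form such pairs, and how tags were filtered is not given. The main cluster of mouse histone genes is known to lie on chromosome 13, but the files do not pair these promoters with genes. In a second cluster of chromosome 13, between 21808044 and 22135077, 0 of 16 such promoters fell, 4 of them in near-identical pairs; in a cluster of chromosome 3 between 96023703 and 96218762, 0 of 7 fell, 2 of them in such a pair, but its 16 promoters of any level were lower by a mean of -0.46 (SE 0.063), with 4 past the threshold. Fewer copies of the segment and the mutation itself stay open and untested.

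A set of 18 promoters had at least 10 CPM in FLT3-ITD cells and at most 2% of that level in double-mutant replicate 2, and all 5 named promoters that fell were among them. In double-mutant replicate 1 they kept 0.48% to 43.1% of the FLT3-ITD level (median 6.62%), and in replicate 3 0.62% to 19.98% (median 3.65%). ITD cells or tags mixed into double-mutant replicate 1 would leave 1 share for all promoters otherwise silent in the double mutant. The set was picked on replicate 2 alone, so its members need not be silent there. Mixing as the whole residue of all 18 promoters is argued against. It may still be the whole residue of some of them. With the spread of the FLT3-ITD level allowed for, the tags of replicate 1 deviated from the pooled share of 10.5% by 44.98 times the variance it gives (chi-square over its degrees of freedom). Among the 6 promoters with at least 50 CPM in FLT3-ITD cells it was 116 times. Both values include the promoter of chromosome 19 at 20465155, which kept 43.1% and did not pass (limma adjusted p = 0.16). The others of the 6 kept 3.69% to 12.1%. Whether the set without that promoter keeps 1 share was not tested. Mixing as a part of the residue cannot be told apart from activity of the promoters themselves. With limits adjusted for the 18 promoters and widened by 2 SD of the FLT3-ITD level, no promoter excluded a share of up to 4.78%. The lowest limit without either was 2.67%, from 1 tag.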
